A study of Caenorhabditis elegans with 2 samples.

How the data were processed

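The study measured where the GATA transcription factor ELT-1 bound DNA in Caenorhabditis elegans, by chromatin immunoprecipitation and sequencing (ChIP-seq) of an eGFP-tagged ELT-1 in whole L3 larvae of mixed sex. Per the labels, the strain OP354 carries an unc-119 mutation and an inserted transgene for tagged elt-1, and the fragment size range was 150 to 350 bp. The labels give 1 group with biological replicates 1 and 2 and no second condition, so no contrast between groups exists. The comparisons are between the replicates, between peaks past the threshold and the other listed regions, and between gene groups. A control entered the authors' peak calls, per the authors' library file lists, and was not analysed here.

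The deposited files are peak lists, on the builds ce11 and ce10. Per the authors' library file lists, relaxed lists were called from each replicate and from both replicates pooled, each with a control. The same lists say that the thresholded list, selected by irreproducible discovery rate (IDR, a measure of how well the ranks of peaks repeat between replicates), was derived from the pooled and the replicate lists. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each deposited peak has a signal value, which is the authors' own and is used only to describe and rank peaks within a list. The deposited −log10 q values reach a highest value shared by many peaks, including all 1910 IDR peaks on ce11, and so do not rank them. The other column used gives the summit as an offset from the peak start, per the deposited files' format. Read depth is unknown, so no interval that needs depth is given.

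Analyses used the ce11 lists with the WBcel235 genome sequence and Ensembl release 115 annotation, which has 19985 protein-coding genes among 46926 genes. No ce10 annotation was used. On ce11 the IDR list was the 1910 strongest peaks of the pooled list of 30000, so using the strongest pooled peaks in its place is no separate alternative. The background for peak comparisons was the 27789 pooled peaks with a summit over 500 bp from every IDR summit. The authors' name for the pooled list is peaks and background, and its −log10 q values go down to 0.0361. Pooled peaks outside the IDR list can therefore be background, not only weaker binding sites. A promoter window ran from 1000 bp upstream to 200 bp downstream of each protein-coding transcript start. Exon, intron and intergenic shares used protein-coding genes only, so intergenic summits there can lie in non-coding genes. Single named peaks were placed against all annotated genes except piRNA genes. GATA sites were searched on both strands as WGATAR (W is A or T, R is A or G) within 50 bp of the summit.

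Shares were compared by 2-sided Fisher's exact tests, chromosomes by exact binomial tests, summit and flanking windows by exact McNemar tests, and replicate overlap by 1000 circular shifts of summits along each chromosome. Signal ranks of peaks with and without a site were compared by a permutation test with 100000 resamples. Benjamini-Hochberg adjustment was applied within each family, and the threshold was 0.05. Intervals are exact 95% Clopper-Pearson intervals that treat peaks or genes as independent, which neighbouring ones are not. The 22 gene lists were fixed before the data were examined, and every listed symbol matched the annotation. The background for gene lists was the 8239 protein-coding genes with a pooled summit in the promoter window. A list's members among these, its background members, were tested against the other background genes. Named genes followed a rule fixed before the data were examined: genes at the 10 strongest IDR peaks, up to 4 members per list by highest signal, all listed GATA factors, and unc-119.

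The tests were checked on simulated peaks. The GATA site test made 3 calls in 100 sets without a difference. With a site written into 30% of windows it found 45.6% where 45.6% was expected. Both values come from the same site search, so this checks the code only. The McNemar test made 11 calls in 200 on uniform positions. With a site written into 30% of windows, the summit share was 40.4% where 40.4% was expected, again a check of the code only. The replicate overlap test made 3 calls in 100 on unrelated positions, and found 59.7% where 59.5% was written. The promoter test made 2 calls in 100. With random pooled peaks in place of IDR peaks, the gene list test made 110 calls in 2200, but the heterochronic list alone was called in 32 of 100. Chromosome tests made 34 calls in 600 on uniform positions, and found X at a mean of 1.37 times its expected number in 100 draws where 1.38 was written. An earlier single draw gave 442 X peaks, by chance the number observed in the data. The signal rank test made 2 calls in 40 shuffled sets. The RNA class test failed this check: on shifted peaks, which have no preference, Fisher's exact test made 124 calls in 200 for short RNA classes. Circular shifts were therefore added for RNA classes after that check, and made 3 calls in 200, although there the simulated peaks were drawn from the same model. RNA class results rest on the shifts, and the Fisher values are given beside them.

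Alternatives set before the data were examined covered windows, sites, backgrounds, overlap rules, stronger peaks, builds and each replicate's own list of 1910 strongest peaks. Values given without a replicate, or with a replicate left out, used the other replicate's 1910 strongest peaks in place of the IDR peaks. Background peaks and genes, where a test had them, still came from the pooled list of both replicates. Chosen after seeing the data were nuclear peaks only, transgene loci left out, the site AGATAA, TGATAA under other settings, single sites against flanking windows, and the shifts for RNA classes. Chromosome distribution and transgene loci were not run on ce10. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.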

Results

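ELT-1, a GATA factor required for epidermal fate, was profiled by ChIP-seq of its eGFP-tagged form in whole L3 larvae, in 2 biological replicates. The thresholded list held 1910 IDR peaks, 1882 on nuclear chromosomes and 28 on the mitochondrial genome, with a median width of 340 bp. The authors' signal values ran from 27.7 to 1900 with a median of 40.8. The relaxed lists held 29029 regions for replicate 1, 30000 for replicate 2 and 30000 for the pooled data. Their lowest −log10 q values were 0.147, 0.0979 and 0.0361, so they can include background. Read depth is unknown.

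The strongest peaks lay in elt-1 itself and on the mitochondrial genome. The second strongest of all IDR peaks, with a signal of 1858, lay in an intron of elt-1 on chromosome IV at 9615363 to 9615965 (ce11). Of the 10 strongest peaks, 6 were mitochondrial, and the highest, at 4422 to 5003 with a signal of 1900, lay in a coding exon of WBGene00000829 and in the window of COX3. The others there were in coding exons of WBGene00010967, ND1 and WBGene00010960 and in an rRNA gene. Mitochondrial peaks had a median signal of 278, against 40.5 for nuclear ones, and 21.4% of their summits had WGATAR within 50 bp, against 30.1% of all mitochondrial positions. These peaks covered 50.7% of the mitochondrial genome, and their source was not tested, as no control signal was used here. The remaining peaks of the 10 were 1335 bp upstream of R02D5.1 (V, 14506744 to 14507079, signal 472), 3976 bp upstream of the nuclear receptor gene nhr-17 (X, 12671669 to 12671972, signal 387) and in a coding exon of the chemoreceptor gene srw-85 (V, 19429631 to 19429956, signal 384). Each of these had AGATAA within 50 bp.

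The strongest peaks of the replicates shared positions far more often than shifted peaks did. Of the 1910 strongest peaks of replicate 1, 54.4% had a summit within 100 bp of one of the 1910 strongest of replicate 2, against a mean of 0.898% under circular shifts (1-sided permutation test p = 0.001, the smallest 1000 shifts can give). Of the IDR peaks, 69.2% were matched among the strongest of replicate 1, 82.0% among those of replicate 2 and 55.1% among both. Among 1746 IDR peaks found in both whole lists, log2 signal in the replicates had a Pearson r of 0.544 and a Spearman rho of 0.442, across peaks, which are not independent replicates. For the 1735 nuclear peaks among these, Pearson r was 0.507 and Spearman rho 0.435. No peak had identical values in both replicate lists.

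IDR peaks lay more often in promoters and intergenic DNA, and less often in exons, than the remaining pooled peaks, which can include background. Promoter windows held 849 of 1910 summits, 44.5% (95% interval 42.2 to 46.7), against 32.0% of the 27789 remaining pooled peaks (odds ratio 1.70, Fisher's exact test p = 1.02e-27). DNA outside protein-coding genes, called intergenic here, held 63.8% against 40.3%. Introns of these genes held 27.1% against 35.1% and their exons 9.11% against 24.6%. The adjusted values by Fisher's exact test were p = 3.2e-88, p = 3.5e-13 and p = 1.6e-63. Outside promoter windows, 617 summits were intergenic, 373 intronic and 71 exonic.

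GATA sites were concentrated at the summits. WGATAR lay within 50 bp of 39.7% of IDR summits (37.5 to 41.9), against 21.1% of the remaining pooled peaks (odds ratio 2.46, Fisher's exact test p = 7.8e-70). Windows 500 bp to the left and right of the same summits had it in 20.99% and 21.99% (exact McNemar p = 3.9e-36 and p = 1.2e-30). The AGATAA form was in 23.2% against 7.27% (odds ratio 3.85, adjusted Fisher's exact p = 3.1e-95) and AGATAG in 9.74% against 3.55% (odds ratio 2.93, adjusted Fisher's exact p = 1.2e-30). TGATAA, in 9.16% against 8.74%, did not pass (odds ratio 1.05, adjusted Fisher's exact p = 0.57), nor did TGATAG, in 3.93% against 3.69% (adjusted Fisher's exact p = 0.57). The TGATAA result depends on the background, the window and peak strength: its odds ratio was 1.48 with a background matched on GC content and promoter status (Fisher's exact p = 4.95e-05) and 1.35 in the stronger 955 peaks (Fisher's exact p = 0.00533), but 0.875 within 100 bp of the summit (Fisher's exact p = 0.0409). Its share in the flanking windows was 9.32% and 10.3% (exact McNemar p = 0.908 and p = 0.277).

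**Figure D1:**
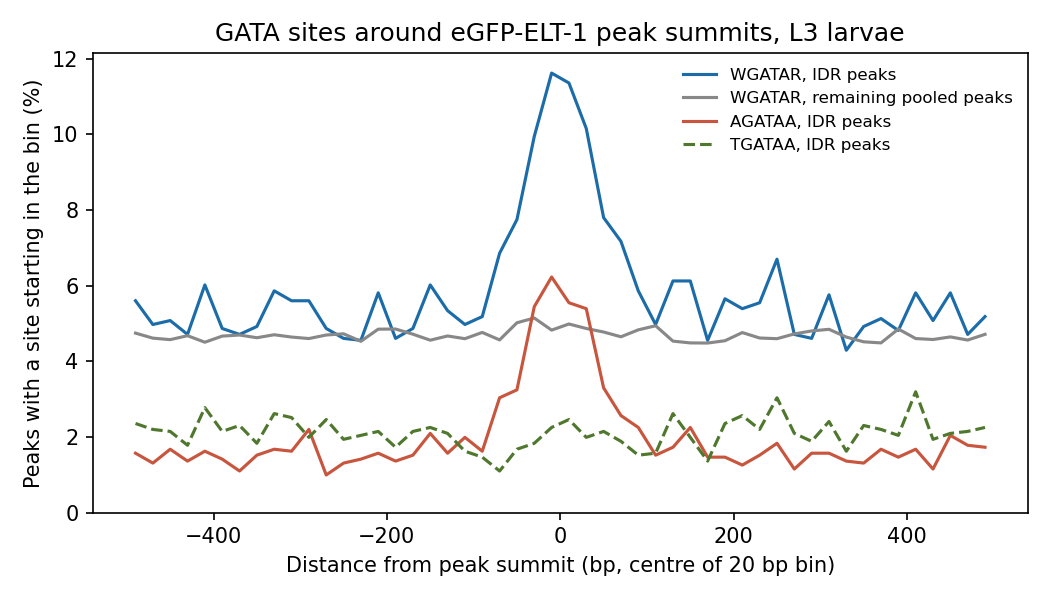
Share of peaks (%) with a site starting in each 20 bp bin, by distance from the summit in bp, for IDR peaks and the remaining pooled peaks. WGATAR in IDR peaks reached 11.6% just left of the summit against 4.83% in the remaining pooled peaks, and TGATAA in IDR peaks was 2.25% in that bin.

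Stronger peaks had the site more often. By 4 bins of signal, WGATAR was present in 52.3% (47.7 to 56.9), 40.8%, 34.8% and 30.8% (26.7 to 35.2) of peaks, from the strongest to the weakest bin. Peaks with the site ranked 9.87 percentile points higher on average than those without (2-sided permutation test p = 1e-05, the smallest 100000 resamples can give).

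The X chromosome carried more peaks than its length predicts, and chromosomes IV and V carried fewer. X held 442 nuclear IDR peaks, 24.9 per Mb, against 17.4 per Mb on the autosomes, and 1.33 times the number expected from length (adjusted exact binomial p = 1.2e-09). Chromosome V had 0.787 times the expected number (adjusted exact binomial p = 3.6e-06) and IV 0.810 times (adjusted exact binomial p = 2.3e-04). Chromosomes I, II and III did not pass, at 1.01, 1.07 and 1.05 times the expected number, but II passed without replicate 1, at 1.12 (adjusted exact binomial p = 0.0343). Against the remaining pooled peaks in place of length, X kept its call at 1.27, and V lost it at 0.933 (adjusted Fisher's exact p = 0.299). In the stronger 955 peaks IV lost it at 0.853 (adjusted exact binomial p = 0.0837).

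**Figure D2:**
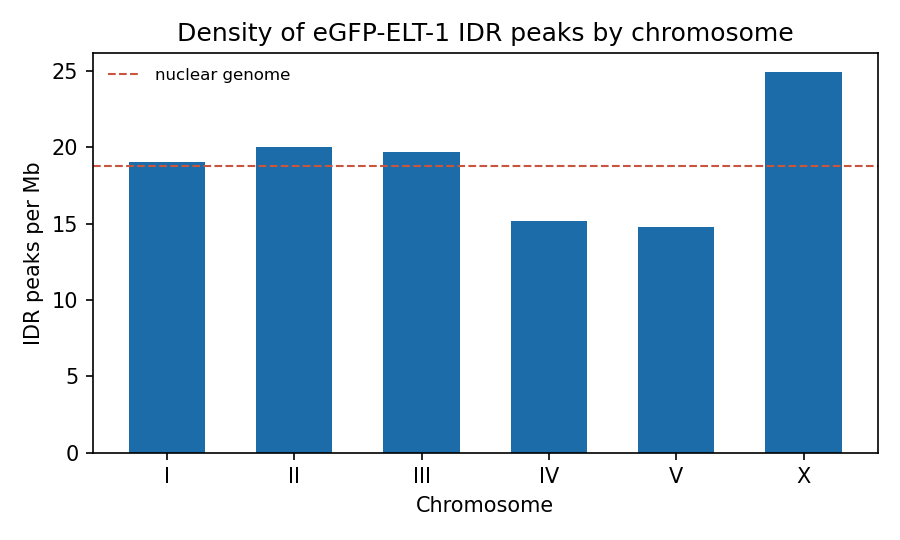
IDR peaks per Mb on each nuclear chromosome, with the nuclear genome as a dashed line at 18.8 per Mb. The X bar stands at 24.9 per Mb and the bars of IV and V at 15.2 and 14.8 per Mb.

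Genes for ribosomal proteins, histones, Hox factors and molting had peaks at their promoters more often than other genes, and chemoreceptor genes less often. In all, 1006 of 19985 protein-coding genes had an IDR summit in the promoter window, which is 12.2% of the 8239 genes with any pooled summit there. Of 22 lists, 5 passed, 4 higher and 1 lower.

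Ribosomal protein genes had a peak in 34 of 72 background members, 47.2% (35.3 to 59.3; odds ratio 6.62, adjusted Fisher's exact p = 4.5e-12). Against all protein-coding genes, with or without a pooled peak, the odds ratio was 15.1 for this list and 0.0573 for chemoreceptor families (adjusted Fisher's exact p = 1.61e-22 and p = 1.03e-16). The strongest were at rpl-3 (III, peak 3867457 to 3867695, signal 227), rpl-20 (IV, 4749978 to 4750189, signal 158), rpl-35 (III, 7854599 to 7854779, signal 143) and rps-12 (III, 5679047 to 5679226, signal 111), all intergenic and none with WGATAR within 50 bp. Histone genes had a peak in 10 of 25 members (odds ratio 4.83, adjusted Fisher's exact p = 0.0030), with his-37 at 85.8, the divergent pair his-67 and his-68 sharing a peak at 64.8, and his-31 at 40.3. With members that share a peak counted once, the histone list no longer passed (odds ratio 3.61, adjusted Fisher's exact p = 0.0529). Nor did it pass in the stronger 955 peaks (2.23, adjusted Fisher's exact p = 0.382) or by nearest transcript start (3.07, adjusted Fisher's exact p = 0.0521).

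Hox genes and their cofactors had a peak in 4 of 6 members (odds ratio 14.4, adjusted Fisher's exact p = 0.015). These were the Hox genes ceh-13 (signal 58.2) and lin-39 (41.2), the Meis-type cofactor gene unc-62 (37.3) and the Pbx-type cofactor gene ceh-20 (34.5), none with WGATAR within 50 bp of these summits. Molting genes had a peak in 5 of 12 members (odds ratio 5.16, adjusted Fisher's exact p = 0.045), among them nhr-23, a nuclear receptor that drives molting, with its strongest peak in an intron (I, 7216207 to 7216374, signal 87.8), myrf-1 (43.7), the period homologue lin-42 (43.3) and the kinase gene nekl-3 (33.8). The molting odds ratio was 3.61 without replicate 1 and 2.67 without replicate 2, neither past the threshold (adjusted Fisher's exact p = 0.153 and p = 0.281), and the call was also lost with shorter or longer windows (2.98 and 2.75, p = 0.333 and p = 0.138). In the stronger 955 peaks the molting odds ratio was 5.45 but did not pass (adjusted Fisher's exact p = 0.158). The myrf-1 summit lay in an exon of a non-coding gene. The Hox call was lost in the stronger 955 peaks, at 8.17, and with the shorter window, at 6.96 (adjusted Fisher's exact p = 0.189 and p = 0.293). Chemoreceptor families had a peak in 3 of 144 members, 2.08% (0.432 to 5.97; odds ratio 0.150, adjusted Fisher's exact p = 1.7e-04), namely str-7, srh-23 and srh-16, with signals of 45.7, 39.7 and 37.8. The chemoreceptor odds ratio was 0.281 without replicate 2 (adjusted Fisher's exact p = 0.00915), and the ribosomal one 3.66 in the stronger 955 peaks (adjusted Fisher's exact p = 0.00468).

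Apart from molting, lists tied to the epidermis and cuticle held peaks without passing the planned Fisher's exact test, and some passed under other settings. Cuticle assembly and apical matrix genes had a peak in 6 of 19 members (adjusted Fisher's exact p = 0.080), including noah-1 (signal 74.4), pdi-2 (36.2), lpr-3 (34.9) and tsp-15 (33.3). This list passed in 5 other settings, among them shared peaks counted once (odds ratio 4.18, adjusted Fisher's exact p = 0.0375) and the nearest transcript start (5.41, p = 0.00123), but in the stronger 955 peaks its odds ratio was 0.904 (adjusted Fisher's exact p = 1). Hedgehog-related ligand genes had a peak in 7 of 28 members (adjusted Fisher's exact p = 0.20), and passed without replicate 2 (odds ratio 3.22, adjusted Fisher's exact p = 0.0407) and under circular shifts (5.57 times the shifted mean, adjusted permutation p = 0.00879), led by grd-10 (98.6), grd-13 (86.9), grd-3 (85.2) and grd-5 (72.1), each with WGATAR within 50 bp. Junction and attachment genes had 4 of 15 (adjusted Fisher's exact p = 0.25), being ifb-1 (96.0), dlg-1 (63.8), ajm-1 (38.6) and vab-10 (33.2). The named ajm-1 summit, in an intron of that gene, also lay in exons of a tRNA gene and a non-coding gene. That summit had no WGATAR within 50 bp, but the other IDR summit in the ajm-1 promoter window did. Summits named for noah-1 and pdi-2 lay in exons of non-coding genes. Among collagen genes, the Dpy, Rol, Sqt, Bli and Lon list had 3 of 17 (sqt-3 61.4, dpy-3 36.98, rol-6 36.3) and the col family 9 of 68 (col-107 73.9, col-3 and col-117 sharing a peak at 70.8, col-65 66.5). The col family passed under circular shifts (2.58 times the shifted mean, adjusted permutation p = 0.0488). Epidermal and seam regulators had 2 of 12, elt-1 and nhr-23, and epidermal defence genes 3 of 15 (osr-1 45.9, nlp-31 and nlp-34 sharing a peak at 31.8). The odds ratio of epidermal defence genes was 1.80, and 3.61 without replicate 1 (adjusted Fisher's exact p = 0.103), that of the col family 1.10, and 1.90 without replicate 2 (adjusted Fisher's exact p = 0.155), and that of cuticle assembly 3.33, and 2.14 without replicate 2 (adjusted Fisher's exact p = 0.281). The odds ratio of seam regulators was 1.44 (adjusted Fisher's exact p = 0.870), 7.90 by nearest transcript start, where it passed (adjusted Fisher's exact p = 5.11e-04), and 0.654 without the transgene loci, of which elt-1 is one (adjusted Fisher's exact p = 1).

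Among the other lists, germline genes had 5 of 15 (adjusted Fisher's exact p = 0.089; mex-5 and rec-8 sharing a peak at 64.8, pie-1 63.1, cgh-1 35.5) and heterochronic genes 3 of 10 (odds ratio 3.09, and 4.81 without replicate 1; adjusted Fisher's exact p = 0.25 and p = 0.103; kin-20 49.3, lin-42 43.3, lin-28 35.0). Germline genes passed with the longer window (adjusted Fisher's exact p = 0.0498) and under circular shifts (5.55 times the shifted mean, adjusted permutation p = 0.0220), and heterochronic genes by nearest start (adjusted Fisher's exact p = 0.00659), a list that was also called often on random peaks. The kin-20 summit, in an intron of that gene, also lay in an exon of a non-coding gene. Wnt pathway genes had 2 of 14 (wrm-1 40.8, lit-1 34.1), the DBL-1 pathway 1 of 6 (sma-9 72.7; odds ratio 1.44, and 8.01 without replicate 2, adjusted Fisher's exact p = 0.0777) and Patched-related receptors 1 of 11 (ptr-18 79.6). Of the tissue markers, which did not pass, neurons had 1 of 22 (unc-18 32.7), body wall muscle 1 of 13 (unc-60 29.3) and none without replicate 1, intestine 0 of 6, which allows a share of up to 45.9%, and pharynx 0 of 2, which allows up to 84.2%. GATA factors had 1 of 5, elt-1.

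**Figure D3:**
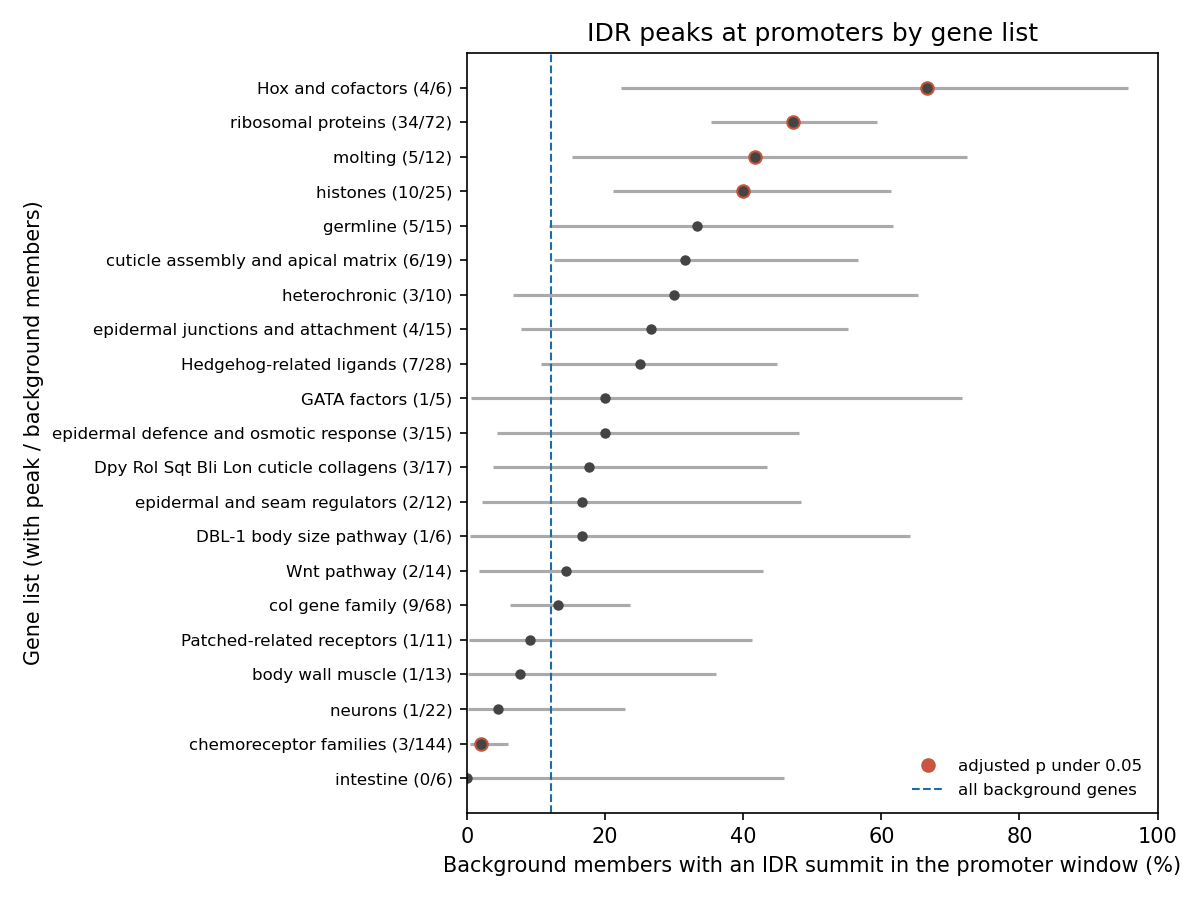
Share (%) of each list's background members with an IDR summit in the promoter window, with exact 95% intervals, for the lists with at least 5 background members. The dashed line marks 12.2% for all background genes, and red points mark the 5 lists past the threshold, with chemoreceptor families at 2.08%.

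Of the transgene's genes, elt-1 had more IDR peaks and higher signal values than unc-119. The elt-1 gene (WBGene00001249, IV, 9614995 to 9620280, plus strand) had 11 IDR peaks within 20 kb and all 11 were among the 1910 strongest of both replicates. After the intronic peak, the strongest were at 9614129 to 9614473, upstream of the gene (signal 375, percentile 99.4), and at 9618110 to 9618393, in an intron (signal 276, percentile 98.9). The unc-119 gene (III, 10902641 to 10908935), which rescues the mutant background, had 3 IDR peaks, in a coding exon (signal 60.5, percentile 77.6), an intron (51.7, percentile 69.0) and the 3' UTR (30.7, percentile 16.5). Only the unc-119 peak in the intron was among the 1910 strongest of both replicates. The other unc-119 peaks were among those of replicate 1 and not of replicate 2. Of the 11 listed GATA factors only elt-1 had an IDR summit in its promoter window. The nearest IDR summit to a transcript start was 1657 bp away for egl-18, 1705 bp for elt-3 and 2866 bp for elt-6, which act in the epidermis. It was 44518 bp away for elt-4, and 50231 bp for elt-2, 76009 bp for elt-7, 21686 bp for end-1, 40512 bp for end-3, 25617 bp for med-1 and 87584 bp for med-2, these last known for roles in the endoderm.

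**Figure D4:**
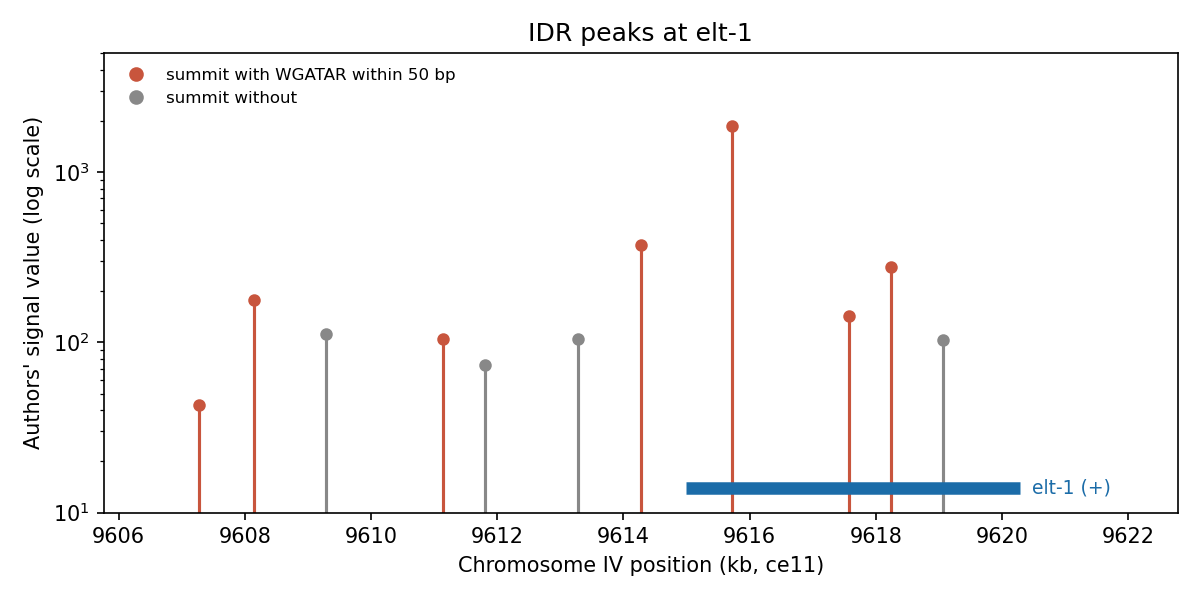
IDR peaks within 20 kb of elt-1 by position on chromosome IV (kb, ce11) and the authors' signal value on a log axis, with the gene as a bar. The strongest stands at 1858, and 7 of the 11 summits, in red, had WGATAR within 50 bp.

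Genes for snoRNA, tRNA and snRNA had more nearby peaks than shifted peaks gave, and pseudogenes fewer. On nuclear chromosomes, an IDR summit lay within 200 bp of 24 of 346 snoRNA genes against 3.45 under shifts, 19 of 612 tRNA genes against 6.03, and 6 of 129 snRNA genes against 1.11. For these, the circular shift permutation test gave adjusted p = 0.0030, p = 0.0030 and p = 0.0048, from raw values of which 0.002 is the smallest 1000 shifts can give 2-sided. Pseudogenes had 4 of 2128 against 65.6 (adjusted permutation p = 0.0030), and miRNA genes 1 of 261 against 2.55 (adjusted permutation p = 0.61). The class of other non-coding genes had 414 against 194 under shifts, 2.14 times as many (adjusted permutation p = 0.0030). In the stronger 955 peaks, snoRNA genes were at 2.88 and tRNA genes at 1.97 times the shifted mean, and neither passed (adjusted permutation p = 0.111 and p = 0.259). With summits inside genes, snRNA genes were at 7.72 times and did not pass (adjusted permutation p = 0.0695), tRNA genes were at 5.24 times, other non-coding genes at 4.91 times and pseudogenes at 0. Within 500 bp, tRNA genes were at 1.98 times, snRNA genes at 3.02 times and pseudogenes at 0.165 times, all past the threshold. Without replicate 2, pseudogenes were at 0.106 times by shifts (adjusted permutation p = 0.00240). With mitochondrial genes included, the planned Fisher's exact test against all other genes gave odds ratios of 1.70 for tRNA (adjusted p = 0.0107), 2.46 for snoRNA (adjusted p = 3.08e-04), 1.60 for snRNA (adjusted p = 0.287), 0.125 for miRNA (adjusted p = 0.00844) and 0.0589 for pseudogenes (adjusted p = 2.07e-22). The miRNA call was lost without replicate 1 (0.378, adjusted Fisher's exact p = 0.116) and without replicate 2 (0.387, adjusted Fisher's exact p = 0.105), and pseudogenes were at 0.106 without replicate 2 (adjusted Fisher's exact p = 1.13e-18). On nuclear peaks the tRNA odds ratio was 1.07 (adjusted Fisher's exact p = 0.717), and in the stronger 955 peaks that of snoRNA was 1.01 (adjusted Fisher's exact p = 0.822) and that of miRNA 0.263 (adjusted Fisher's exact p = 0.232). With shifts on all peaks, tRNA genes with a peak were 1.41 times the shifted mean (adjusted permutation p = 0.0384), against 3.15 times on nuclear peaks. Fisher's exact test put other non-coding genes lower than all other annotated genes, at 0.416 (adjusted Fisher's exact p = 7.87e-53). The shifts compare with moved positions instead, so these values do not conflict. Against the nuclear genome, promoter windows were favoured by IDR peaks (odds ratio 2.21), and no shift ratio for protein-coding genes is given. A class above its shifted mean was therefore not told apart from a general preference for DNA near genes. Fisher's exact test also called short classes on simulated peaks with no preference. The shifts do not keep a peak's place in chromosome arms or centres, so both have limits.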

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

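Nuclear peaks only, transgene loci left out, the site AGATAA, and TGATAA under other settings were chosen after seeing the data. So were single sites against flanking windows and circular shifts for RNA classes. The other alternatives were set before. Among the main results, 36 alternative values with a test kept direction and side of the threshold, 23 counts stayed within 1.5 times and 6 did not. The GATA enrichment was lost with the site TGATAA (odds ratio 1.05) and turned with the shuffled control WAGTAR (0.726, Fisher's exact p = 8.3e-06). The control was thus not neutral, and the peak sets also differ in sequence beyond GATA sites. With the background matched on GC content and promoter status the WGATAR odds ratio was 2.86. With a replicate left out the WGATAR odds ratio was 2.23 to 2.25. The number of gene lists called went from 5 to 2 in the stronger 955 peaks, which are fewer, to 3 with the short promoter window, and to 9 with circular shifts, whose background is not limited to genes with a pooled peak. Those 9 are the same 5 and the col, cuticle assembly, Hedgehog-related and germline lists. RNA classes called by Fisher's exact test, which failed its check on simulated peaks, went from 5 to 3 in the stronger 955 and to 2 with summits inside genes. Other non-coding genes were below other genes by that test, and above shifted peaks by the shifts. Circular shifts on nuclear peaks also called 5, but with snRNA in place of miRNA. These went to 3 in the stronger 955, where snoRNA and tRNA were lost, to 4 with summits inside genes, and stayed at 5 within 500 bp and with a replicate left out. The cause was not tested except where the construction gives it.

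Reversals among single results mostly had no call on either side. TGATAA went to 0.875 within 100 bp (Fisher's exact p = 0.0409) and 0.880 in promoter windows. Chromosome I went to 0.976 in the stronger 955, 0.951 against remaining pooled peaks and 0.940 to 1.00 with a replicate left out, and III to 0.913 against remaining pooled peaks. In the stronger 955, cuticle assembly went to 0.904 and Patched-related receptors to 1.63. The short window gave 0.534 for Dpy and related collagens, 1.16 for Patched-related receptors and muscle, 0.771 for Wnt and 0 for DBL-1. The long window gave 1.16 for Patched-related, 0.940 for DBL-1 and 1.01 for neurons, and the nearest start 2.21, 0.776 and 2.55. Shifts gave 1.37 for Patched-related and 1.13 for muscle. Wnt was 0.614 to 1.20 with a replicate left out. Without the transgene loci, GATA factors went to 0 and seam regulators to 0.654, since elt-1 is in both. With summits inside genes, tRNA went to 0.701 and snRNA to 0.992. Other non-coding genes went to 2.14 with shifts, on all or nuclear peaks, where the reference is shifted peaks and not other genes. By shifts, miRNA genes went to 1.42 within 500 bp and 1.17 to 1.19 with a replicate left out. Chromosome distribution and transgene loci on ce10 were not run, and the strongest pooled peaks are the IDR list itself. Read depth is unknown.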

Other observations

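The 6-mer scan, the density window and the tests on even signal at elt-1, on its GATA sites against other IDR peaks, on mitochondrial or transgene peaks and on a hidden TGATAA enrichment were chosen only after the result was seen. Among the strongest nuclear peaks away from elt-1, 4 are named here, chosen after their values were seen. They lay in an intron of fasn-1, a fatty acid synthase gene (I, 8985892 to 8986273, signal 343), in the 5' UTR of pmt-2, a phosphoethanolamine methyltransferase gene (V, 4628478 to 4628781, signal 273), in an intron of the sestrin gene sesn-1 (I, 32643 to 32911, signal 233) and in an intron of the GATA factor gene egl-18 (IV, 1911272 to 1911661, signal 229). The pmt-2 and sesn-1 summits had AGATAA within 50 bp, and the fasn-1 and egl-18 summits had no WGATAR there. An exploratory scan covered 2080 6-mers in nuclear peaks, against 6018 remaining peaks matched on GC content and promoter status. It ranked AGATAA first, at 23.3% against 5.87%. In all, 550 6-mers passed the threshold, 253 higher and 297 lower, so the matched sets still differed widely in sequence. With a window of 45.3 kb, 11 peaks were counted at elt-1 and 12 around position 6843027 of chromosome II, so elt-1 did not have the highest density.

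The IDR peaks gathered at elt-1 could come from extra copies of the locus in the transgene. The strongest peak was 17.2 times the median of the others there, and all 10 others lay above the nuclear median of 40.5. These had passed the IDR threshold, however, and 22 pooled peaks lay there against 11 IDR peaks. Within 20 kb of unc-119 lay 21 pooled peaks against 3 IDR peaks, with signals of 60.5, 51.7 and 30.7. The genes thus had similar numbers of pooled peaks and differed in IDR peaks. WGATAR was under 63.6% of the 11 summits (30.8 to 89.1), against 21.1% of remaining pooled peaks (exact binomial p = 0.00275). IDR peaks in general have more sites, and against the 39.8% of other nuclear IDR peaks the test did not pass (Fisher's exact p = 0.128), nor among peaks with a signal of at least 57.7, with 6 of 10 against 54.1% (Fisher's exact p = 0.760), so a part of these sites in the gathering stays open. Copy number was not measured here, so an even rise from extra copies stays open, and copies and binding cannot be told apart.

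Peaks at ribosomal protein gene promoters had few GATA sites, 12.9% of 31 summits (3.63 to 29.8). That was not above the 21.3% of remaining pooled promoter peaks (Fisher's exact p = 0.378) and was below the 33.9% of other IDR promoter peaks (Fisher's exact p = 0.0180), which argues against recruitment through WGATAR near the summit. With each shared peak counted once the odds ratio was 7.38 (Fisher's exact p = 1.11e-13), which argues against clustering of genes that share peaks. Signal that tracks heavily transcribed DNA, whatever the factor, may also give such peaks and was not tested, as no control signal was used here.

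AGATAA was enriched at IDR summits more than TGATAA. With the background matched on GC content and promoter status, the AGATAA odds ratio was 2.89 times that of TGATAA (bootstrap interval 2.28 to 3.72), which argues against those features as the whole cause of the difference. Without mitochondrial peaks and those at elt-1 and unc-119, the AGATAA odds ratio was 3.86, but these are 42 peaks and leaving them out could not have brought it under 3.49, so this decides nothing. Whether TGATAA is enriched at all stays open: its odds ratio was 1.48 with the matched background and 1.35 in the stronger 955 peaks (Fisher's exact p = 0.00533), and peaks with it ranked 8.85 percentile points higher in signal (permutation p = 1.60e-04), but within 100 bp of the summit the odds ratio was 0.875 (Fisher's exact p = 0.0409), and its share within 50 bp, 9.16%, was not above the 9.32% and 10.3% in flanks of the same peaks (exact McNemar p = 0.908 and p = 0.277). The design has 1 group, so no biological difference between groups was tested for any of these patterns.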
